A study of Mus musculus with 2 samples.

How the data were processed

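The series holds 2 RNA-seq libraries from mouse kidney, 1 from a normal kidney with a genotype labelled wild type, without doxycycline, and 1 from a kidney tumour of an animal labelled Tet-OSKM/mPer2-luc that received doxycycline. In Tet-OSKM animals the reprogramming factors Oct4 (gene Pou5f1), Sox2, Klf4 and c-Myc are placed under a promoter that doxycycline switches on, and mPer2-luc is a luciferase reporter of the clock gene Per2. Per the labels' protocols, chimeric animals were made by injecting embryonic stem cells that carry these transgenes into blastocysts of a C57BL/6 and DBA/2 hybrid. That protocol stands with both libraries, so whether the normal kidney came from a chimeric animal is left open, and the sex of the animals is not given in the sources used here. Per the same protocols, total RNA from homogenised tissue was depleted of ribosomal RNA and made into libraries with a kit that keeps the strand of the transcript.

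The authors deposited whole-number read counts over the exons of 32958 UCSC knownCanonical gene models, with a total of 40408775 reads for the normal library and 33169818 reads for the tumour library per the file headers. The submitters' processing notes name bcl2fastq, STAR 2.5.0c and HOMER, without role or order, and the mouse genome build mm10. How reads that map to several places were treated, and which strand setting was used in counting, is not given in the sources used here. Genes with near-identical copies elsewhere in the genome are therefore uncertain, among them ribosomal protein genes, replication-dependent histones, globins, Cyp2a4, Ugt2b38, Hbb-b2, Pou5f1, Nanog and Dppa5a. The authors also deposited RPKM values, which equalled the count divided by transcript length and by the header total and scaled to the usual units for every model, with a largest difference of 1.80e-06. Coordinates are those of the deposited table, counted from 1 on mm10. Of the 22675 symbols that the GENCODE M21 annotation of the same assembly places on the same chromosome and strand, 22588 (99.6%) overlapped its gene.

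Counts of the table were used as deposited. Where several models shared a symbol (708 of 30744 symbols, 2922 models), the model with the most reads over both libraries stood for it. A gene was taken as measured with at least 20 reads over both libraries, which held for 16326 symbols. Library sizes were scaled with TMM (edgeR 4.0.16 in R 4.3.3), which gave factors of 0.824 for the normal and 1.21 for the tumour library. The ratio of TMM-scaled counts, tumour over normal, was taken for each gene, with an exact conditional (Clopper-Pearson) 95% interval from the 2 counts. These intervals and all others printed with a fold or a share of reads cover counting error only, and PCR copies are not told apart from separate molecules. A count of 0 was replaced by a floor of 3 counts, which equals 0.124 CPM in the normal and 0.119 CPM in the tumour library. The fold is then given as "at least", a bound set by that floor. The lower limit of the 95% counting interval lies below it, for Pou5f1 at 2937-fold against 3611-fold. Counts of 1 or 2 were kept, so a gene with 0 reads can rank as less extreme than one with 1 read. A gene was called higher or lower in the tumour library when its ratio was at least 2-fold and its interval excluded 1. With 1 library per group no p-value across genes was computed, and CPM values in the text are TMM-scaled. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

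Before the data were examined, 45 gene lists were written from textbook knowledge of the kidney, the circadian clock, pluripotent cells, other cell types, proliferation and metabolism. They hold 815 entries, of which 800 were found in the table and 734 were measured. For each list the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and its percentile among them describes these 2 libraries. Lists of germ layer and germ line genes (2 lists) were added after the data had been seen. The genes named in the text were fixed by a rule at the same time as the lists. It takes every member of the reprogramming factor list and of both core clock lists, and the 8 genes with the largest ratio in each direction among those with a mean of at least 10 CPM and an interval wholly beyond 2-fold. In each other list it takes the 3 members with the largest ratio in the direction of the median and, where at least 2-fold, the largest in the other direction, among members with a mean of at least 1 CPM. It also takes the 4 genes with the most reads in each library. Some genes that the rule takes, and the counts and median of the list of clock activators, are not reported here. Further members that complete a count of 5 or fewer, or that are singled out, were chosen after their values were seen.

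The calls and the intervals were tested on simulated counts drawn from the means and sizes of the 2 libraries. The simulation held counting error only, with 200 changed genes, as many higher as lower. Every other gene had the same mean in both libraries. It therefore does not test the scaling or the calls where most genes differ, as here, where 59.2% of measured genes were called. In the simulated comparison of kidney tumour with normal kidney, 100 of 100 genes changed 3-fold and 100 of 100 changed 8-fold were called in the right direction, and 48 of 16107 unchanged genes (0.298%) were called. The true ratio lay within the 95% interval for 95.3% of 16307 genes. The list percentiles were checked apart from the counts, on random values from a normal distribution. There 4 of 100 random lists lay outside the 5th to 95th percentiles. Those values did not depend on expression, so the use of matching on expression was not tested. The alternatives tried were DESeq2 1.42.0 size factors, plain CPM of all counted reads, the header totals, no filter on low counts, a minimum of 100 reads, a prior count of 2, the deposited RPKM plus 0.1, thresholds of 4-fold and 1.5-fold, a 95% interval wholly beyond 2-fold, and the sum of the models of each symbol. Counting coding models only was added after the data had been seen.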

Results

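The transcriptomes of 1 normal mouse kidney and 1 kidney tumour that arose during in vivo reprogramming were profiled by total RNA-seq. The series title poses the question of how the circadian clockwork is altered in such tumours, and the design implies a single comparison, tumour against normal kidney. With 1 library per group, the difference has no replicate check, so the values below compare these 2 libraries and not the conditions. Reads over exons came to 29258428 in the normal library (72.4% of its total) and 20836819 in the tumour library (62.8%), and 18357 and 20546 gene models had at least 1 read. Intervals are 95% intervals for counting error.

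Transcripts of nephron segments were lower in the tumour library almost throughout, and those of pluripotent and dividing cells were higher. Within the clock, the period gene Per2, the nuclear receptors Nr1d1 and Nr1d2 and the output factors Dbp, Tef and Hlf were lower in the tumour, whereas Arntl, which encodes BMAL1, and Cry1 were higher. Clock, the partner of Arntl, and Rora, an activator of Arntl, were lower too, 2.93-fold and 6.67-fold. Of 16326 measured genes, 5099 were at least 2-fold higher in the tumour library and 4566 at least 2-fold lower, so that 52.8% of the calls were higher. That share was 67.6% with plain CPM, 62.5% with header totals and 62.6% with the deposited RPKM plus 0.1. Under these settings the median log2 ratio of all measured genes moved from 0.08 up by 0.56, 0.35 and 0.32. At least 8-fold differences were found for 1986 genes higher and 1495 genes lower. Among the measured genes, 224 had 0 reads in the normal and at least 100 in the tumour library, against 28 the other way round. Across the measured genes, which are not independent replicates, Spearman's correlation between the 2 libraries was 0.655.

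**Figure D1:**
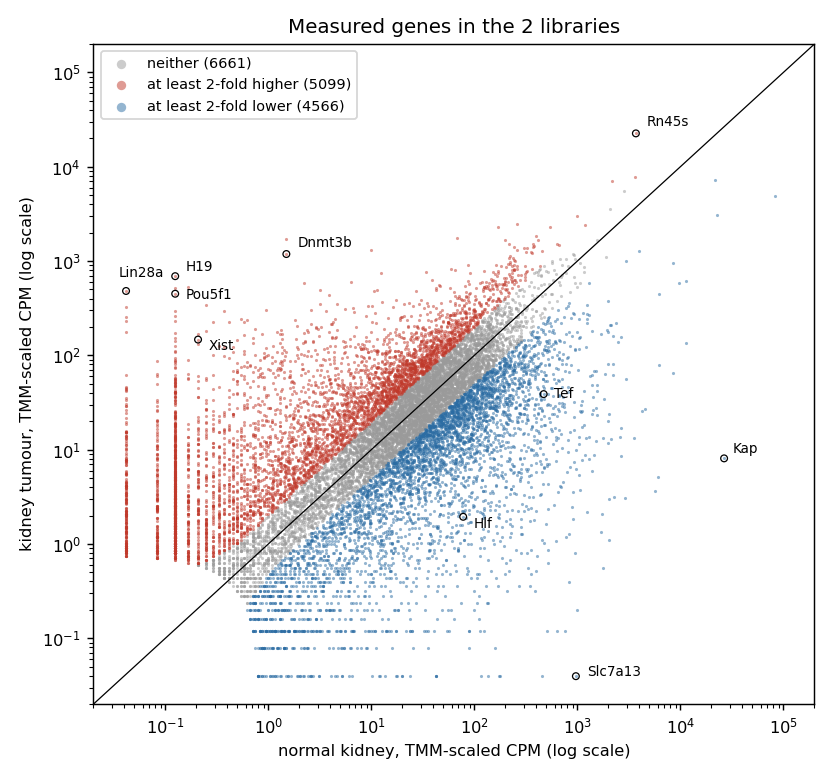
TMM-scaled CPM of each measured gene in the normal kidney (horizontal, log scale) and in the kidney tumour (vertical, log scale), 1 library each, with a line at equal values and counts of 0 drawn at the floor of 3 counts. The 5099 genes at least 2-fold higher in the tumour lie above the line and the 4566 genes at least 2-fold lower lie below it, with Lin28a and Slc7a13 at the far ends. Each of these has 1 read in its lower library and so lies beyond the floor at which genes with 0 reads are drawn.

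The most abundant transcripts differed between the libraries. In the normal kidney the 4 models with the most reads were AK018753, a mitochondrial model (chromosome M, 1149 to 3703) over most of the 16S ribosomal RNA and Nd1 genes, with 2001962 reads, Kap, an androgen-regulated proximal tubule transcript, with 639918 reads, DQ539915, a mitochondrial model (5327 to 6938) over the cytochrome c oxidase subunit I gene, with 547877 reads, and the nuclear long noncoding RNA Malat1 with 518288 reads. In the tumour they were Rn45s, the precursor of ribosomal RNA, with 569883 reads, the translation elongation factor Eef1a1 with 194896 reads, Malat1 with 183227 reads and Rmrp, the RNA of a ribosomal RNA processing enzyme, with 177282 reads. Mitochondrial models took 10.6% of counted reads in the normal library and 1.22% in the tumour (exact Clopper-Pearson 95% intervals 10.61% to 10.63% and 1.216% to 1.226%). Rn45s, which had passed through ribosomal RNA depletion, took 0.304% (0.302% to 0.306%) and 2.73% (2.728% to 2.742%).

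The reprogramming factors themselves were higher in the tumour library for 4 of 4 genes. Pou5f1 (chromosome 17, 35506032 to 35510777) had 0 reads in the normal and 11358 in the tumour library, at least 3611-fold higher, and Sox2 (chromosome 3, 34650005 to 34652460) had 0 and 3820 reads, at least 1214-fold higher. Klf4 (chromosome 4, 55527137 to 55532475) was 3.997-fold higher (interval 3.30 to 4.87), with 5.47 CPM in the normal and 21.9 CPM in the tumour library. Myc (chromosome 15, 61985341 to 61990361) was 6.12-fold higher (4.77 to 7.94), with 3.03 and 18.5 CPM. The exon count of a gene does not by itself tell transcripts of the transgene from those of the endogenous gene.

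Pluripotency genes followed, with 22 of 24 measured members at least 2-fold higher, 1 lower and 1 neither, and a median log2 ratio of 8.73 that lay above all 10000 matched random lists. Of the 24 members 13 had 0 reads in the normal library, so the size of that median depends on the floor. Lin28a, an RNA-binding protein that blocks maturation of let-7 microRNAs, had 1 read in the normal and 12152 in the tumour library (11593-fold, interval 2080 to 457930). L1td1, an RNA-binding protein of embryonic stem cells, had 1 and 8294 reads (7912-fold, 1420 to 312560), and the homeobox factor Nanog had 1 and 4507 reads (4300-fold, 771 to 169860). The exception was Tfcp2l1, a factor of naive pluripotency that is also made in collecting duct and distal tubule cells, which was 8.60-fold lower (8.24 to 8.98). All 10 measured members of the list of clock-related factors of pluripotent cells were higher, with a median of 4.25. Pluripotency and cell cycle genes were higher almost throughout, so this list does not separate the clock from pluripotency or cell division. Among them the de novo DNA methyltransferase Dnmt3b was 794-fold higher (573 to 1134), its cofactor Dnmt3l had 0 reads in the normal library and was at least 705-fold higher, and Uhrf1, which brings Dnmt1 to replicated DNA, was 118-fold higher (91.9 to 154).

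Core clock genes differed in direction. Arntl (chromosome 7, 113207465 to 113314126), the partner of CLOCK, was 2.57-fold higher (2.08 to 3.20), its paralog Arntl2 4.09-fold (2.69 to 6.41), the cryptochrome Cry1 (chromosome 10, 85131700 to 85185054) 3.97-fold (3.44 to 4.59) and Nfil3, a repressor at D-box elements, 2.07-fold (1.60 to 2.68). Clock (chromosome 5, 76209868 to 76304548) was 2.93-fold lower (2.73 to 3.15), at 122 CPM in the normal and 41.5 CPM in the tumour library, and with plain CPM its log2 ratio was -0.99, short of 2-fold. Rora and Rorb, nuclear receptors that activate Arntl, were lower as well, Rora 6.67-fold (6.07 to 7.34) and Rorb 2.26-fold (1.13 to 4.75), the last from 28 and 13 reads and short of 2-fold with plain CPM, header totals and RPKM (log2 ratios of -0.62, -0.82 and -0.31). Npas2, a paralog of Clock, had 31 and 19 reads and an interval that included no difference.

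In the list of repressors and the PAR bZIP output arm, 8 of 12 members were lower, none was higher and 4 were neither, with a median of -1.70 at percentile 0.41 of the random lists. The PAR bZIP factors, which drive rhythmic output genes through D-box elements, showed the largest differences: Hlf (chromosome 11, 90336535 to 90390917) was 40.1-fold lower (30.2 to 54.4), Tef 12.1-fold (11.4 to 12.9) and Dbp (chromosome 7, 45705247 to 45710203) 8.60-fold (7.38 to 10.1). Per2 (chromosome 1, 91415982 to 91459328), the gene of the reporter named in the genotype of the tumour animal, was 8.25-fold lower (7.09 to 9.65), at 61.7 CPM in the normal and 7.48 CPM in the tumour library. Nr1d2 was 5.03-fold lower (4.69 to 5.40) and Nr1d1 4.54-fold (3.66 to 5.68), both repressors of Arntl. Per3 was 2.33-fold lower (2.14 to 2.55) and the E-box repressor Bhlhe40 2.09-fold (1.93 to 2.26), and both were short of 2-fold with plain CPM, header totals and RPKM, with log2 ratios of -0.67, -0.87 and -0.85 for Per3 and -0.50, -0.71 and -0.70 for Bhlhe40. Per1 (log2 ratio -0.86), Ciart (-0.83) and Cry2 (-0.38) had ratios below 2-fold, and Cry2 turned to 0.18 with plain CPM. Bhlhe41, with a log2 ratio of 0.90, passed 2-fold with plain CPM (1.46), header totals (1.25) and RPKM (1.12). Time of day at collection is not given in the sources used here, and transcripts of this arm vary over the day in normal kidney.

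**Figure D2:**
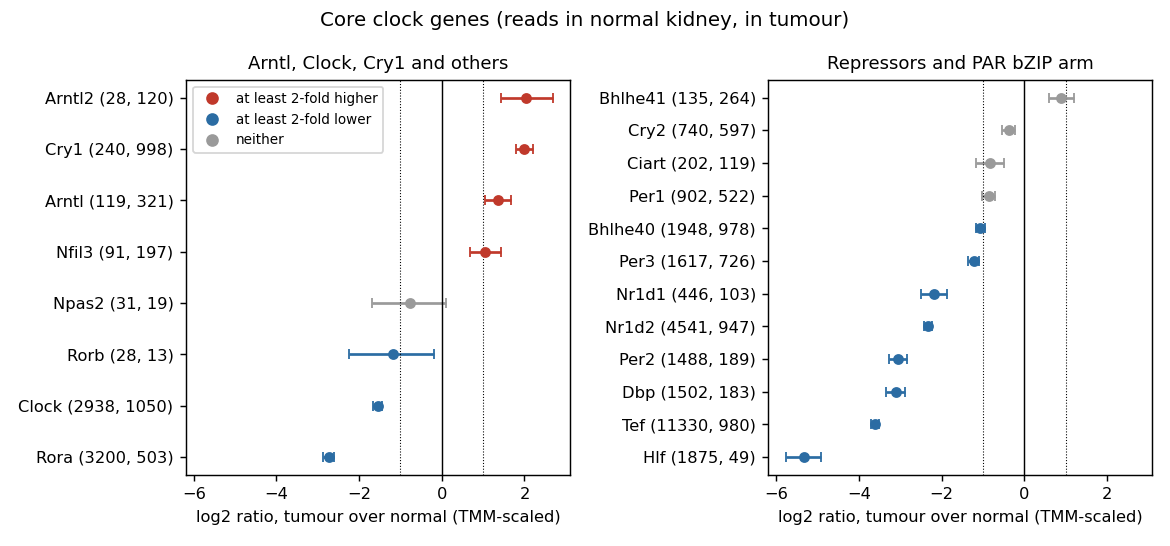
Log2 ratio, tumour over normal, of 8 clock genes, among them Arntl, Clock and Cry1 (left) and the 12 repressor and PAR bZIP arm genes (right), 1 library each, with 95% counting intervals as bars, dotted lines at 2-fold and the read counts of the normal and tumour library beside each name. On the right 8 of 12 genes (6 with plain CPM) lie at least 2-fold below 0, Hlf lowest at -5.33, and on the left 4 genes lie at least 2-fold above 0 and 3 at least 2-fold below it (1 with plain CPM).

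Of the kinases, ligases and cofactors of the clock, 7 of 17 were higher, 2 lower and 8 neither, with a median of 0.28 at percentile 77.1. The 3 largest were Timeless, 13.8-fold higher (11.6 to 16.4), Kpna2, an importin, 12.6-fold (11.5 to 13.9), and Tipin, the Timeless partner at replication forks, 9.98-fold (8.81 to 11.3). Genes of cell division were higher throughout, as given below, so these 3 values do not separate the clock from cell division. The deubiquitinase Usp2, a clock output gene, was 14.8-fold lower (12.6 to 17.5), and the ligase subunit Fbxl21 was the other lower member, with a log2 ratio of -2.81. Among clock-controlled kidney genes, 15 of 25 were lower, 5 higher and 5 neither, with a median of -1.69 at percentile 0.06. Of these 25 genes 7 are also in other lists, among them the principal cell genes Aqp2, Avpr2 and Scnn1a, so the list does not separate the clock from the lower nephron segment genes described below. The sodium-proton exchanger Slc9a3 was 214-fold lower (119 to 428), the monooxygenase Fmo2 45.5-fold (40.9 to 50.7) and the water channel Aqp2 42.1-fold (30.8 to 59.1), while the cyclin-dependent kinase inhibitor Cdkn1a was 5.93-fold higher (4.25 to 8.47). The other higher members were Hif3a, Leo1, Tardbp and Wee1, with log2 ratios of 2.09, 1.86, 1.09 and 1.02.

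Nephron segment genes were lower almost without exception. In the proximal tubule list 38 of 39 measured members were lower, with a median of -7.39 below all random lists. Slc7a13, an amino acid transporter of the late proximal tubule, had 23293 reads in the normal and 1 in the tumour library (24416-fold lower, 4382 to 964440), Kap was 3288-fold lower (2867 to 3791) and the inositol oxygenase Miox 1843-fold lower (1275 to 2774). The member that was higher was Umps, an enzyme of pyrimidine synthesis, at 2.73-fold (2.56 to 2.93). In the loop of Henle and distal convoluted tubule list 18 of 20 were lower and 2 neither, with a median of -5.78. The growth factor Egf was 948-fold lower (760 to 1200), the FGF23 co-receptor Kl 502-fold (376 to 686) and the calcium-binding protein Calb1 211-fold (157 to 289). The neither members were Trpm7 and Wnk1, with log2 ratios of -0.97 and -0.74.

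All 12 principal cell genes of the collecting duct were lower, with a median of -4.73, led by the sodium channel subunit Scnn1g at 50.8-fold (34.2 to 78.8), Aqp2 at 42.1-fold and the vasopressin receptor Avpr2 at 39.9-fold (22.1 to 80.6). Of 13 intercalated cell genes 12 were lower, with a median of -5.08, led by the anion exchanger Slc26a4 at 178-fold (101 to 345), the ammonia channel Rhcg at 101-fold (70.4 to 152) and the carbonic anhydrase Car12 at 37.3-fold (32.9 to 42.5). Kit, a receptor tyrosine kinase that is also made in mast and germ cells, was 4.26-fold higher (3.79 to 4.79). Of 15 podocyte genes 9 were lower, 2 higher and 4 neither, with a median of -1.31 at percentile 2.18. The basement membrane collagens Col4a4 and Col4a3 were 36.1-fold (32.2 to 40.6) and 34.0-fold (30.8 to 37.6) lower and the factor Tcf21 12.1-fold lower (8.30 to 18.4), whereas Wt1 was 3.28-fold higher (2.70 to 4.002) and the phospholipase Plce1 was higher with a log2 ratio of 1.38.

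The remaining largest differences on the lower side were in proximal tubule and other metabolic genes. Slco1a1, an organic anion transporter, had 10933 and 1 reads (11460-fold lower, 2056 to 452700), the glucuronosyltransferase Ugt2b38 18341 and 3 reads (6408-fold, 2192 to 31078), the methyltransferase Inmt 15303 and 0 reads (at least 5347-fold lower) and the acyl-CoA synthetase Acsm3 23917 and 5 reads (5014-fold, 2148 to 15444). Slc22a28, of the organic anion transporter family, had 4261 and 1 reads (4466-fold, 801 to 176460), Acmsd, an enzyme of tryptophan breakdown, 4181 and 1 reads (4383-fold, 786 to 173150) and the cytochrome P450 Cyp2a4 12107 and 3 reads (4230-fold, 1447 to 20516). On the higher side, besides Lin28a, L1td1, Nanog and Pou5f1, they were the imprinted gene Zdbf2 with 1 and 6459 reads (6162-fold, 1106 to 243420), the ubiquitin ligase Trim71, a let-7 target, with 1 and 5888 reads (5617-fold, 1008 to 221900), the imprinted noncoding RNA H19 with 0 and 17443 reads (at least 5546-fold) and Trh, the precursor of thyrotropin-releasing hormone, with 0 and 12968 reads (at least 4123-fold).

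Genes of the embryonic kidney were divided, with 13 of 27 measured members higher, 9 lower and 5 neither and a median of 0.10 at percentile 35.9. Lin28b had 0 reads in the normal library and was at least 869-fold higher, and Fgf8, a growth factor of the early nephron, had 0 and 341 reads and was at least 108-fold higher. Hoxd10, a posterior patterning gene, was 12.1-fold lower (8.45 to 17.8), and the kidney lineage factors Pax8, Lhx1 and Pax2 had log2 ratios of -2.76, -1.77 and -1.30. Of 26 oncofetal and imprinted genes 22 were higher, 1 lower and 3 neither, with a median of 5.21 above all random lists. H19 led, followed by Rian, a noncoding RNA of the Dlk1-Meg3 cluster, at 3192-fold (1246 to 11718) and Igf2bp3, an oncofetal RNA-binding protein with 3 reads in the normal library, at 1369-fold (468 to 6642). The imprinted adaptor Grb10 was 3.08-fold lower (2.82 to 3.37).

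Genes of cell division were higher without exception, 35 of 35 in the cell cycle list with a median of 5.93 and 20 of 20 replication-dependent histones with a median of 5.78. The mitotic kinases Bub1, Plk1 and Bub1b were 388-fold (231 to 709), 151-fold (84.1 to 303) and 131-fold (97.7 to 181) higher. The linker histones Hist1h1b and Hist1h1a were 1360-fold (625 to 3707) and 154-fold (123 to 195) higher, and Hist1h2ae, with 0 reads in the normal library, was at least 325-fold higher. In the list of cyclin-dependent kinase inhibitors and p53 targets 10 of 19 were higher, 2 lower and 7 neither, with a median of 1.55 at percentile 99.7. Eda2r, of the TNF receptor family, was 30.3-fold higher (19.5 to 50.01), Trp53 itself 9.86-fold (8.61 to 11.3) and the apoptosis effector Bbc3 7.43-fold (4.998 to 11.4). Cdkn2c was 9.48-fold lower (6.15 to 15.3), and Ccng1 was the other lower member with a log2 ratio of -1.03. Of 15 polycomb and chromatin genes 13 were higher, with a median of 2.10, led by the helicase Hells at 111-fold (88.7 to 141), the H3K27 methyltransferase Ezh2 at 14.7-fold (12.7 to 17.1) and the remodeller Chd7 at 13.2-fold (12.02 to 14.5). Bmi1 was 3.46-fold lower (3.12 to 3.86).

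Ribosomal protein genes were higher for 33 of 34 members, with a median of 1.96, between 1.96 and 2.52 over the scalings tried. Among them Rpl3 was 4.57-fold (4.45 to 4.69) and Rps27a 4.48-fold (4.32 to 4.64) higher. Genes often used as references spread widely, with 5 of 15 higher, 3 lower and 7 neither and a median of 0.45. Rps18, Rpl13a and Eef1a1 were 5.05-fold (4.88 to 5.24), 4.28-fold (4.18 to 4.39) and 2.11-fold (2.09 to 2.13) higher, and Actb and Gapdh were the other higher members with log2 ratios of 1.02 and 1.01. Sdha and B2m were among the lower members, with log2 ratios of -2.49 and -1.49.

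Metabolic genes moved apart. All 24 genes of fatty acid oxidation and peroxisomes were lower, with a median of -3.87 below all random lists, led by the peroxisomal enzymes Ehhadh, 138-fold (120 to 158), Acaa1b, 131-fold (106 to 165), and Acox2, 97.0-fold (69.6 to 140). Of 30 nuclear genes of oxidative phosphorylation 29 were lower, with a median of -1.82 at percentile 3.80, led by the complex I subunit Ndufa1 at 5.94-fold (5.47 to 6.45) and the complex II subunits Sdhc at 5.83-fold (5.52 to 6.15) and Sdha at 5.64-fold (5.46 to 5.82). Mitochondrial models stood at 1.22% of tumour reads against 10.6%, as given above. In the normal library 2001962 of the 3106237 mitochondrial reads fell on AK018753, which covers most of the 16S ribosomal RNA gene. That share therefore does not stand for respiratory chain transcripts alone. Of 20 glycolysis genes 11 were higher, 1 lower and 8 neither, with a median of 1.02 at percentile 99.1. The glucose transporter Slc2a3 was 1159-fold higher (837 to 1655), the lactate transporter Slc16a3 382-fold (231 to 683) and the hexokinase Hk2 317-fold (211 to 500), whereas Hk1 was 3.38-fold lower (3.15 to 3.64). Hypoxia response genes went both ways, with 5 of 16 higher, 4 lower and 7 neither and a median of -0.05 that turned positive with plain CPM, header totals and RPKM. Ndrg1 was 27.4-fold (26.2 to 28.6), Car9 9.11-fold (6.06 to 14.3) and Vegfa 4.21-fold (3.96 to 4.48) lower, and the glucose transporter Slc2a1 was 12.2-fold higher (11.5 to 13.0).

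Among the other cell types of the kidney, endothelial genes were lower for 13 of 18 members, with a median of -1.74 at percentile 0.03. The VEGF receptor Kdr was 15.8-fold (13.9 to 18.1), the factor Erg 11.6-fold (8.09 to 17.3) and the diaphragm protein Plvap 9.32-fold (8.19 to 10.7) lower, and Vwf was 2.79-fold higher (2.03 to 3.89). Stromal and extracellular matrix genes were higher for 19 of 29 members, with 1 lower and 9 neither and a median of 2.12 above all random lists. Fibrillin-2 (Fbn2) was 379-fold (148 to 1394), versican (Vcan) 140-fold (98.7 to 204) and the protease inhibitor Timp1 68.1-fold (34.3 to 158) higher, and Col14a1 was 5.84-fold lower (5.31 to 6.42). Macrophage and monocyte genes were higher for 13 of 18 members, with a median of 1.77 at percentile 99.9. The integrin Itgam was 14.7-fold (10.96 to 20.2), lysozyme (Lyz2) 11.4-fold (10.2 to 12.7) and Cd68 8.14-fold (6.25 to 10.8) higher, whereas the class II antigen presentation genes H2-Aa, H2-Ab1 and Cd74 were lower, H2-Aa by 5.68-fold (5.05 to 6.42) and the others with log2 ratios of -2.30 and -1.95.

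Few lymphocyte and neutrophil genes were measured. Of 5 T, NK and B cell genes 4 were higher, among them Lck at 8.88-fold (5.76 to 14.3), Cd4 at 6.42-fold (3.39 to 13.4) and Cd22 at 6.20-fold (2.93 to 15.1), Cd79b was the other with a log2 ratio of 1.75, and Cd8a was lower at -1.65. The median of 2.63 lay at percentile 82.3 and was -0.068 without a filter on low counts. All 5 measured neutrophil genes were higher, with a median of 2.18 at percentile 77.7, among them S100a9 at 7.43-fold (4.24 to 14.04), S100a8 at 6.13-fold (2.75 to 16.1) and Csf3r at 3.48-fold (2.10 to 6.03), and Ltf and Retnlg had log2 ratios of 1.15 and 2.18. All 6 measured erythroid genes were lower, with a median of -1.88 at percentile 1.31. The anion exchanger Slc4a1, which intercalated cells also make, was 34.9-fold lower (24.0 to 52.7), and the globins Hbb-b2 and Hbb-bs were 4.47-fold (3.69 to 5.44) and 3.01-fold (2.83 to 3.20) lower.

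Injury and inflammation genes were higher for 14 of 24 members, with 5 lower and 5 neither and a median of 2.07 at percentile 99.97. Serpina3n, an acute-phase protease inhibitor, had 1 and 281 reads (268-fold, 47.7 to 10625), Timp1 was 68.1-fold higher and the keratin Krt20 59.3-fold (29.8 to 138). Krt7 was 6.85-fold lower (6.09 to 7.73), and the other lower members were Fga, Fgg, Clu and Fgb, with log2 ratios of -2.44, -2.27, -2.02 and -1.14. Epithelial adhesion genes were divided, 8 of 20 higher, 7 lower and 5 neither, with a median of 0.63 at percentile 94.6. Cdh6, Esrp1 and Grhl2 were 7.52-fold (5.73 to 10.03), 5.78-fold (5.21 to 6.44) and 5.48-fold (4.81 to 6.28) higher, and the tubular tight junction gene Cldn2 was 40.6-fold lower (36.8 to 44.8). Mesenchymal transition genes were higher for 10 of 16 members, with 2 lower and a median of 1.91 at percentile 99.6. Fibronectin (Fn1) was 14.2-fold (13.4 to 14.9), Itga5 12.3-fold (10.2 to 15.1) and the metalloproteinase Mmp14 8.83-fold (7.49 to 10.47) higher, and the lower members were Foxc2, 4.48-fold (2.29 to 9.58), and Snai2, with a log2 ratio of -1.77. Wnt and beta-catenin targets were higher for 9 of 16 members, with 3 lower and a median of 1.86 at percentile 99.6. The Wnt effectors Lef1 and Tcf7 were 109-fold (49.6 to 297) and 108-fold (46.1 to 334) higher and the antagonist Dkk1 42.5-fold (18.0 to 132), whereas Sp5 was 3.05-fold lower (2.25 to 4.19), beside Rnf43 and Sfrp1 with log2 ratios of -1.52 and -1.07. Immediate early and heat shock genes were higher for 8 of 19 members, with 2 lower and a median of 0.57 at percentile 82.4. Fos, Egr2 and Ier2 were 11.7-fold (6.34 to 24.0), 11.1-fold (4.48 to 35.4) and 10.3-fold (8.27 to 13.1) higher, and Ier3, at 5.38-fold (4.68 to 6.20), and Zfp36, with a log2 ratio of -1.52, were lower.

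Genes of tissues other than kidney were present in the tumour library. Neural genes were higher for 15 of 16 measured members, with a median of 5.16 above all random lists. The neuronal tubulin Tubb3 had 0 and 1038 reads (at least 330-fold higher), the migration gene Dcx 1 and 330 reads (315-fold, 56.1 to 12472) and the neural progenitor factor Sox1 0 and 461 reads (at least 146-fold). Cartilage and bone genes were higher for 9 of 11 members, with a median of 4.58 at percentile 99.99. The cartilage collagens Col2a1, Col11a1 and Col9a2 had 0 and 1278 reads (at least 406-fold higher), 2 and 446 reads (213-fold, 58.5 to 1762) and 0 and 329 reads (at least 104-fold), whereas the phosphatase Alpl, also made in proximal tubule, was 6.15-fold lower (5.87 to 6.46). Skeletal muscle genes were higher for 6 of 7 members, with a median of 4.21 at percentile 99.7, among them the embryonic myosin Myh3 with 0 and 167 reads (at least 53.1-fold), Acta1 with 1 and 50 reads (47.7-fold, 8.18 to 1921) and Actc1 with 0 and 62 reads (at least 19.7-fold).

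In the adipocyte list 3 of 6 members were higher, 2 lower and 1 neither, with a median of 1.61 at percentile 83.1 that was -1.23 with at least 100 reads. Cfd had 0 and 105 reads (at least 33.3-fold higher), Adipoq and Cidec had log2 ratios of 2.87 and 3.36, Pparg was 1.27-fold higher with an interval that included no difference, and Lpl was 20.01-fold lower (18.7 to 21.4), beside Fabp4 at -1.23. Of the adrenal list 2 genes were measured, Chga with 0 and 97 reads (at least 30.8-fold higher) and Star with 39 reads in each library, for a median of 2.44 that was -0.068 without the filter. Of 4 urothelium genes Upk3b and Trp63 were lower, with log2 ratios of -2.53 and -1.82, Shh was higher at 1.15 and Upk1a was neither at 0.32, which gave a median of -0.75 at percentile 11.5. Hepatocyte genes were lower for 6 of 7 members, with a median of -3.37 at percentile 0.14. Albumin (Alb) had 260 and 0 reads (at least 90.8-fold lower), transthyretin (Ttr) was 84.5-fold (64.3 to 113) and Apob 22.1-fold (21.03 to 23.3) lower, and Apoa1 was 3.72-fold higher (2.22 to 6.52).

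**Figure D3:**
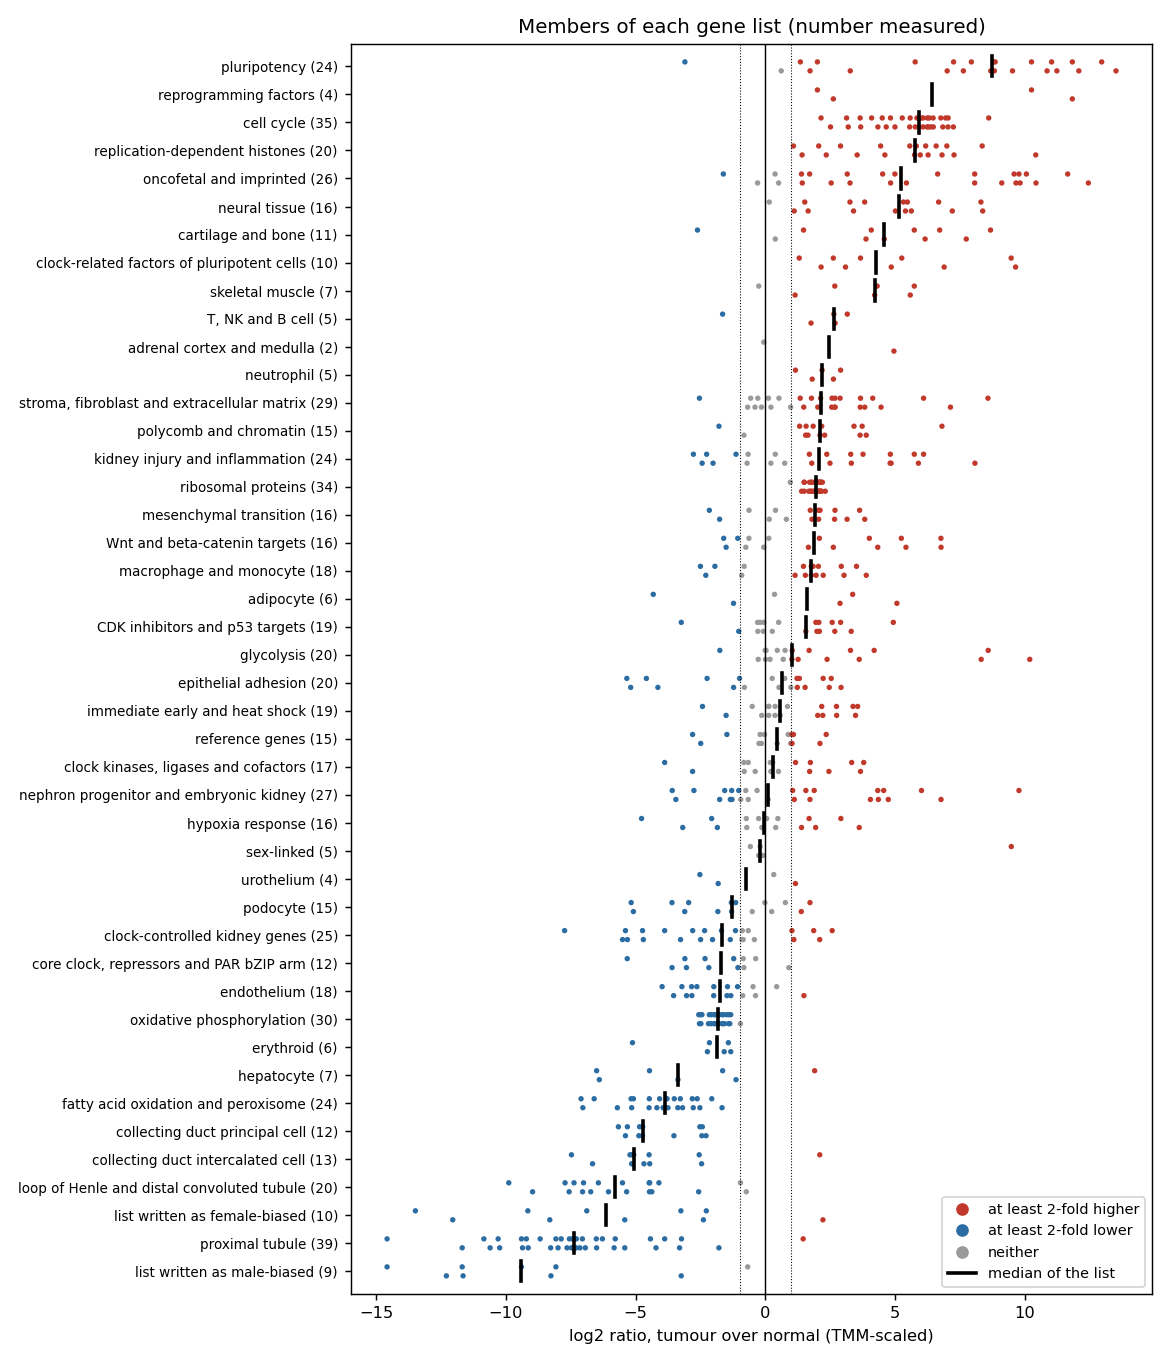
Log2 ratio, tumour over normal, of each measured member (points) of 44 gene lists, with the list's median as a black bar, dotted lines at 2-fold, counts of 0 at the floor of 3 counts and lists ordered by median, 1 library per group. Pluripotency genes lie at the top with a median of 8.73, and the list written as male-biased and proximal tubule genes lie at the bottom with medians of -9.40 and -7.39.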

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

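No called gene took the opposite call under any of the 12 alternatives that tested it. That outcome was nearly fixed in advance, since a ratio would have to cross from 2-fold one way to 2-fold the other. The largest shift of the median log2 ratio of all measured genes was 0.56, with plain CPM. Of the 9665 calls 9641 were kept with DESeq2 size factors and 8396 with plain CPM. Counting coding models only was the test chosen after the results had been seen, and it gave 4657 genes higher and 4176 lower. The cause was not tested for any of the following values. With a 4-fold threshold, 3023 genes were higher and 2573 lower, embryonic kidney genes 8 higher and 3 lower, and proximal tubule genes 0 higher. With plain CPM, 5 embryonic kidney genes were lower, and they also numbered 5 with RPKM and 5 with the whole interval beyond 2-fold. Among clock repressors 1 gene, Bhlhe41, was higher with plain CPM, header totals, RPKM and a 1.5-fold threshold. The interval of a list median was taken from the ordered log2 ratios of its members, or from their full range in the shortest lists. It shows the spread between genes and not counting error. List medians moved beyond their intervals with plain CPM for macrophages (2.32), T, NK and B cells (3.19), erythroid genes (-1.32), cell cycle (6.49), oxidative phosphorylation (-1.26) and ribosomal proteins (2.52). They did so with header totals for cell cycle (6.28), oxidative phosphorylation (-1.47) and ribosomal proteins (2.32), and with RPKM for erythroid genes (-1.14), oxidative phosphorylation (-1.47) and ribosomal proteins (2.32). Medians that changed sign were those of T, NK and B cells (-0.068) and adrenal genes (-0.068) without a filter on low counts and of adipocyte genes (-1.23) with at least 100 reads, settings that admit or remove members with few reads. Other medians, among them those of hypoxia, embryonic kidney, sex-linked and urothelium genes, also changed sign but stayed within their intervals. For embryonic kidney genes that interval ran from -1.29 to 4.04. Staying within such wide intervals is a weak check, and these medians are counted below as having stayed. Over all pairs of a result and an alternative setting, medians stayed within their intervals 343 times, counts within lists stayed within 1.5-fold 141 times and counts of genes 22 times, and the log2 ratios of named genes stayed within their counting intervals 1343 times and left them 351 times, under plain CPM, header totals or RPKM. Abundant tubule transcripts that shift the scaling were weighed as a source of the low tubule values. The proximal tubule median stayed at -6.84 or lower under every setting. A change of scaling adds the same constant to every log2 ratio, and the largest shift was 0.56, so this outcome was nearly fixed in advance. It shows only that shifts of the size seen between these settings do not account for the low values. Depth limits calls to genes with some 20 reads, and folds of genes with 0 to 3 reads in either library are bounds or wide intervals.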

Other observations

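Genes of early embryonic germ layers and of the germ line were looked at after the data had been seen, as were the tests on Xist and on the transgene, whereas the tests on the clock were fixed beforehand. Of 20 measured germ layer and primed pluripotency genes 18 were higher in the tumour library, 2 (Sox17 and Sox7) were neither, and the median log2 ratio was 7.49. Fgf5 and Otx2, markers of the primed epiblast, had 0 reads in the normal library and 911 and 2039 reads in the tumour, at least 289-fold and 648-fold higher. Lefty2, an antagonist of Nodal, had 0 and 3554 reads (at least 1130-fold), the endoderm factor Foxa2 0 and 273 reads (at least 86.8-fold), and the mesoderm factor Eomes 5 and 495 reads (94.4-fold, 40.2 to 292). All 13 measured germ line genes were higher, with a median of 5.71, among them Dazl with 1 and 1045 reads (997-fold, 179 to 39413), Stra8 with 1 and 731 reads (697-fold, 125 to 27582) and Ddx4 with 6 and 171 reads (27.2-fold, 12.2 to 75.1).

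Of 9 genes in the list written as male-biased in kidney 8 were lower, with a median of -9.40, led by Slc7a13, Acsm3 and Kap, and Odc1 was neither at -0.69. Of 10 genes in the list written as female-biased 9 were lower, with a median of -6.15, led by Slco1a1, Cyp2a4 and the organic anion transporter Slc22a7 (570-fold lower, 262 to 1554), and Abcc3 was 4.63-fold higher (3.46 to 6.29). That list holds Slco1a1 and Cyp2d9, which are known as male-predominant in mouse, so its values do not stand for female-biased genes.

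The first pattern weighed is that of the core clock, with 8 of 12 repressor and PAR bZIP genes lower in the tumour. Collection of the 2 kidneys at different times of day may account for part of it. Of 2 groups of opposite phase that were fixed beforehand, Arntl, Npas2, Clock, Cry1 and Nfil3 had a median log2 ratio of 1.05 and Dbp, Nr1d1, Nr1d2, Per3, Ciart, Tef and Hlf one of -2.33. Within the first group Clock went against the higher members, with a log2 ratio of -1.55, Npas2 was neither at -0.77 with an interval that included no difference, and Rora and Rorb, activators of Arntl outside both groups, were lower at -2.74 and -1.17. The 1.05 therefore describes those 5 genes and not the activators of the clock as a whole. Opposite signs were among the outcomes set beforehand for a difference in time. Lower Nr1d1 and Nr1d2, repressors of Arntl, could give such signs without it, so the signs do not decide the question. A general loss of kidney-specific transcripts was tested by the percentile of the repressor arm, 0.41, below the 2.5th percentile set beforehand as arguing against it, but the proximal tubule list itself lay at percentile 0, so that this bound does not separate a clock change from a change of cell types. Both explanations stay open beside a clock change in the tumour cells themselves, which was not tested.

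The second pattern is Xist, the noncoding RNA of the inactive X chromosome, with 5 reads in the normal and 3710 in the tumour library (708-fold, 303 to 2181) beside transcripts of the Y chromosome in both. Of 5 sex-linked genes measured, Xist was higher and the 4 Y-linked genes were neither, with a list median of -0.21, and the antisense partner Tsix had 4 and 200 reads. Reads counted without strand are argued against, since an antisense mitochondrial model that overlaps AK018753 held 0.0748% of that model's reads in the normal and 0.462% in the tumour library. The overlap covers 1533 of the 2554 bases of AK018753. How many of the AK018753 reads fell within it is not known, so the strength of this check is uncertain. A mixture of male cells with female host cells, which a chimeric animal could hold, would lower the Y-linked genes, but the median log2 ratio of Ddx3y, Uty, Eif2s3y and Kdm5d was -0.23 and ran from -0.24 to 0.32 over the settings, with Uty, Eif2s3y and Kdm5d turning positive with plain CPM, header totals and RPKM. That range neither requires nor excludes added cells without a Y chromosome, so such a mixture and Xist expression within cells with a Y chromosome cannot be told apart.

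The third pattern is the origin of the Pou5f1 and Sox2 reads. If the transgene is transcribed as a single RNA carrying all 4 factors, the lower of the Klf4 and Myc read densities per coding base, 0.343 reads per base for Myc against 10.7 for Pou5f1, bounds what it may contribute. That bound came to 3.20% of the Pou5f1 and 8.62% of the Sox2 reads, which argues against the transgene as the main source. A hypothesis that remains is that most Pou5f1 and Sox2 reads come from the endogenous genes, and it rests on the assumed structure of the transgene.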
